A study of Drosophila melanogaster with 32 samples.

How the data were processed

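Total RNA from cultures of Drosophila melanogaster cells was sequenced in 32 libraries. Each library was one passage of one of 3 cell lines, named R1, R4 and R5. A passage is one round of splitting a culture into fresh medium. Per the labels, cells grew in Schneider's medium with serum and antibiotics, RNA was extracted with TRIzol, ribosomal RNA was depleted with a Ribo-Zero kit made for human, mouse and rat, and libraries were made with a ScriptSeq kit. The origin and genotype of the lines are not given in the sources used here.

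The deposited files hold counts, 1 raw count per gene and library. Per the labels, the authors used TopHat 1.4.1, Bowtie 0.12.8 and bedtools on the BDGP5 (dm3) genome. The roles of these tools, the counting rule, the strand setting and the annotation release are not given in the sources used here, so reads of overlapping genes, of antisense partners and of multicopy families cannot be assigned with certainty. Each file lists 15253 entries, of which 2 name no gene and were left out, which left 15251 genes. Symbols came from the BDGP6.54 annotation, which was used for names, chromosome arms and the order of neighbouring genes, and for exon length in 1 test. It was matched by gene ID for 9370 genes, by locus tag for 5002 and by synonym for 90, and 754 and 35 genes kept the symbol or ID of the file. Because the counts rest on an older genome build, no coordinates are given. No genome sequence was used, so base composition was not analysed here.

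The total count per library ran from 7760446 to 18213927. The most abundant gene, mt:lrRNA, took 3.20 to 5.48% of the counts of a library. Genes with a CPM (the usual unit of a read count scaled to library size) of at least 1 in at least 3 libraries were tested, 9183 in all. No pair of libraries was identical. There were no molecular identifiers, so the counting intervals and floors given below cover counting error only. A gene without a read in a group was given a floor of 3 counts over the group, and 1 to 3 reads were given a ratio with an exact (Clopper-Pearson) 95% counting interval.

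The series text puts passages 2 to 4 in an early, 4 to 11 in an intermediate and 16 to 19 in a late stage. Passage 4, named in both, was taken as early, and passage 12 of R4, named in none, was left out of all comparisons, which left 31 libraries. Successive passages of a line are samples of 1 culture, so the line was the replicate for the comparison of stages. Counts were summed per line and stage to 9 libraries, scaled by trimmed mean of M values (TMM), and tested with edgeR 4.0.16 (quasi-likelihood F test) with stage as factor and line as block, which left 4 residual degrees of freedom. Deviations from the stage mean correlated across genes at a mean r of 0.42 between stages of 1 line, so the lines pair the libraries. Deviations from the mean of a line and stage correlated between lines at the same passage at 0.11 to 0.73 at early and -0.07 to 0.08 at late, so passage number pairs the early libraries too; it was used as a block in an alternative only. Genes are not independent replicates in these correlations.

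For comparisons within and between lines the 31 libraries were fitted in 9 groups of line and stage, with 22 residual degrees of freedom, and differences among lines used joint F tests. The p-values of this fit measure the spread between successive passages of a culture, not between cultures. All p-values were adjusted over genes or lists by the Benjamini-Hochberg method, with a threshold of 0.05. CPM are TMM-scaled. Fitted log2 changes carry a standard error (SE) and CPM a standard deviation (SD), between 3 lines or between the passages of a group.

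Gene lists were written from general knowledge of fly tissues and pathways before the data were examined, and the 29 with at least 5 measured members were tested with camera (limma 3.58.1, preset correlation 0.01) on log2 CPM with a prior count of 2. The list of endoderm and gut genes had fewer members measured and was not tested. Listed members PPO1, vas, Ns3, Xrp1 and mt:ND4 were matched to no gene. Named genes also followed a rule fixed before the data were examined. It took the 8 highest rises and falls from early to late among called genes with the same sign in all 3 lines and at least 10 CPM in the higher stage, and 2 members of each called list. To these it added 12 genes named in every case, genes called in both steps with opposite signs, for each line 5 genes at late and 3 at early with the largest excess over both other lines, and 3 genes per line whose change differed most.

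The method was tested on simulated data. Of genes changed 4-fold, 87% were recovered in the comparison of stages and of genes changed 2-fold 46%, with 5 false calls among 138. The simulated data held no lasting differences between lines, no trend over passages and no deviating library. These rates therefore need not hold for the real data. Alternatives covered the scaling, the filter, the stage of passages 4 and 12, DESeq2 1.42.0, limma-trend, libraries as samples, the block, passage number as a covariate and each line or library left out. The runs without passage 2 and without passage 19 of R5 were added after the data were seen. R 4.3.3 and Python 3.11.15 with matplotlib 3.10.9 were used.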

Results

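The transcriptomes of 3 Drosophila melanogaster cell lines were followed by RNA sequencing while the cultures turned into continuous lines. R1 was sampled at passages 2, 3, 4, 5, 7, 8, 10, 11, 16, 17 and 19, R4 at passages 2, 3, 4, 5, 6, 7, 9, 11, 12, 16, 17 and 19, and R5 at passages 2, 3, 4, 6, 7, 8, 16, 17 and 19. The early stage (passages 2 to 4) and the late stage (passages 16 to 19) held 3 libraries per line. The intermediate stage (passages 5 to 11) held 5 libraries of R1, 5 of R4 and 3 of R5. Total counts per library ran from 7760446 (R1 at passage 11) to 18213927 (R5 at passage 2).

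The libraries of the earliest passages lay together on the first principal component of log2 CPM (31.8% of the variance), at 64.7 for R1, 75.8 for R4 and 70.0 for R5 at passage 2. On the second component (18.0%) the late libraries of R5 lay between -62.7 and -59.7, while the late libraries of R1 and R4 lay between -14.9 and 14.6. R4 at passage 4 lay at 4.69 on the first component, apart from the other early libraries of R4 at 75.8 and 55.5.

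**Figure D1:**
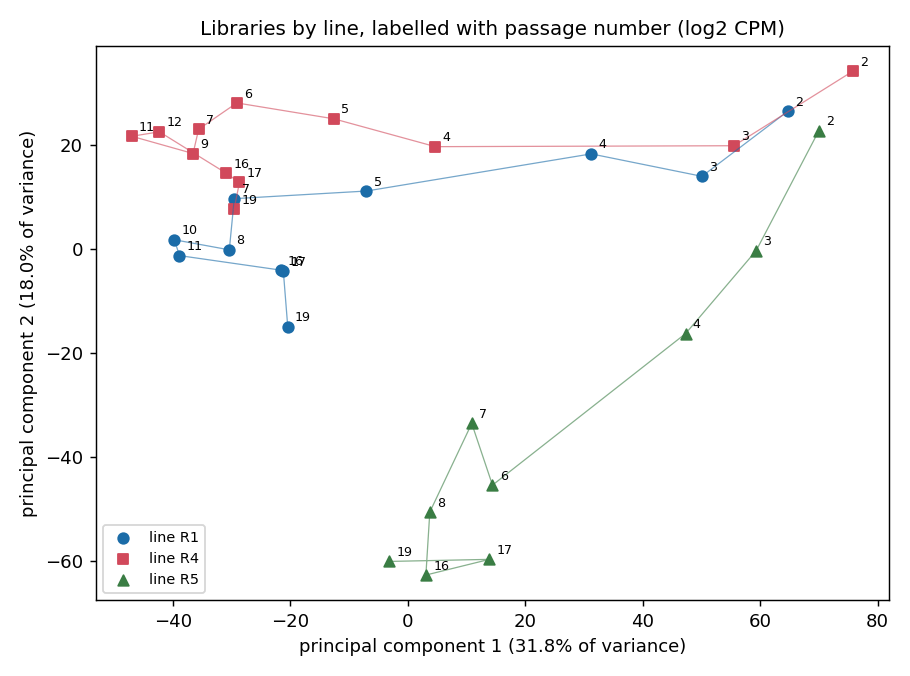
Position of the 32 libraries on the first (31.8% of the variance) and second (18.0%) principal components of log2 CPM, 1 point per library, coloured by line and labelled by passage. Passage 2 of each line lies between 64.7 and 75.8 on the first component, and the late R5 libraries lie between -62.7 and -59.7 on the second.

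The first question was which transcripts differed between the first passages and the established cultures on average over the 3 lines. This comparison does not require a change in each line. Among 9183 genes, 967 changed from early to late, 365 upward and 602 downward. traffic jam (tj, FBgn0000964, chromosome arm 2L), which encodes a large Maf transcription factor of the gonadal soma, fell from 155 ± 61.6 CPM (SD, n = 3 lines) at early to 8.28 ± 2.30 at intermediate and 0.108 ± 0.0467 at late. Its log2 change was -10.46 ± 0.30 (SE), with an adjusted p of 0.000121 (edgeR quasi-likelihood test). At passage 2 it stood between 141 and 299 CPM in the 3 lines. IM33, an immune-induced secreted peptide, fell from 19.5 ± 13.3 to 0.0403 ± 0.0423 CPM (log2 -8.48 ± 1.002, adjusted p = 0.00939). Without R4 at passage 2 the early mean of IM33 was 11.2 CPM (log2 -7.59), and without R1 at passage 5 the intermediate mean of tj was 5.203.

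The other large falls ended in 0 to 3 reads over all late libraries. CG15369 fell from 15.5 ± 12.9 CPM to no read, at least 491-fold lower against the floor. Without R4 at passage 2 its early mean was 6.89 CPM and this limit 242-fold. CG14072 fell from 40.5 ± 15.0 CPM to 3 reads, an early to late ratio of 1291 (95% counting interval 441 to 6262). CG1468 ended at 2 reads, with a ratio of 1007 (95% counting interval 279 to 8321), as did CG34166, with a ratio of 953 (95% counting interval 264 to 7875). CG15293 also ended at 2 reads, with a ratio of 606 (95% counting interval 168 to 5012). The cuticle protein gene Cpr49Ag ended at 3 reads, with a ratio of 450.1 (95% counting interval 154 to 2185). Without R4 at passage 2 the ratio of CG1468 was 587.9, and without R5 at passage 2 that of CG15293 was 394. Within single lines much of the early mean came from passage 2. Without it, CG15293 went from 3.29 to 1.65 CPM in R1, 14.4 to 1.35 in R4 and 15.2 to 3.93 in R5. CG1468 went from 4.27 to 2.09, 31.2 to 3.86 and 21.3 to 9.70, and CG14072 from 54.9 to 32.1, 30.7 to 13.1 and 27.8 to 16.4. The ratios therefore describe the mean of the early stage, not passages 3 and 4 alone. Leaving out a late library that held reads gave higher ratios: CG14072 to 3526 (R5 at passage 16), CG1468 to 1804 (R1 at passage 16) or 1827 (R5 at passage 17), CG34166 to 1655 (R1 at passage 17) or 1729 (R5 at passage 17), CG15293 to 1038 (R4 at passage 16) or 1115 (R5 at passage 19) and Cpr49Ag to 1173 (R1 at passage 17). The counting intervals do not cover the dependence on early libraries. Their adjusted p lay between 0.000324 (CG15293) and 0.00691 (Cpr49Ag).

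CG34334 rose from 0.724 ± 0.192 to 12.1 ± 1.05 CPM, by 4.11 ± 0.42 on the log2 scale (adjusted p = 0.00637, edgeR), and in each of the 3 lines. RpS5b, a paralog of the ribosomal protein gene RpS5a (reads shared by the 2 genes were not analysed here), rose from 13.1 ± 6.77 to 61.3 ± 58.1 CPM (log2 1.99 ± 0.34, adjusted p = 0.0220). His-Psi:CR31614, a histone pseudogene whose counts are uncertain because histone genes are multicopy, rose from 2.48 ± 0.764 to 21.5 ± 19.0 CPM (log2 2.84 ± 0.32, adjusted p = 0.00856). Kots (0.669 ± 0.124 to 10.4 ± 10.1 CPM), CG31337 (1.73 ± 0.353 to 28.1 ± 29.1) and CG7991 (1.74 ± 0.7097 to 20.05 ± 21.5) rose by 3.43, 3.26 and 2.94 on the log2 scale, with adjusted p of 0.0293, 0.0478 and 0.0392. CG32407 (1.73 ± 0.0577 to 11.9 ± 9.90 CPM) and ssp6 (2.92 ± 0.384 to 16.7 ± 16.4) rose by 2.62 and 2.03, with adjusted p of 0.0433 and 0.0491. Without R5 at passage 19 the late mean of CG7991 was 10.1 CPM (log2 2.25), and without R4 at passage 4 the early mean of RpS5b was 8.485 CPM (log2 2.45). CG31337, CG32407 and ssp6 lost the call with the stricter filter (adjusted p = 0.0545, 0.0504 and 0.0584), with passage 4 as intermediate (0.0546, 0.0610 and 0.0536) and with 12, 7 and 15 of the 31 libraries left out in turn (adjusted p up to 0.0914, 0.0601 and 0.0688). CG31337 and ssp6 lost it also with total counts (0.0519 and 0.0551), without the line block (0.121 and 0.103) and with passage 12 added (0.0508 for both), and ssp6 with median of ratios (0.0505) and without passage 2 (0.0650). RpS5b (0.127) and CG7991 (0.0858) lost it without the line block, RpS5b (0.0523) and Kots (0.0522) without R4 at passage 4, and CG7991 without R1 at passage 5 (0.0531), R4 at passage 4 (0.0516), R4 at passage 19 (0.0511) or R5 at passage 16 (0.0515).

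The number of calls depended on the lines used. Without R1 the count was 61 genes (4 higher, 57 lower) and without R4 34 genes (0 higher, 34 lower), against 1047 without R5 (408 higher, 639 lower). No rise was thus called without R4. A fit without a line also had fewer residual degrees of freedom. Of 29 named genes called in this comparison, 4 (tj, CG14072, CG15293 and CG34166) passed with any line left out, while 18 lost the call without R1, 25 without R4 and 4 without R5. With the line block left out the count was 484. Scaling to total counts alone gave 212 rises and 653 falls. Without passage 2 of every line the count was 644, and without R4 at passage 2 alone it was 625.

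**Figure D2:**
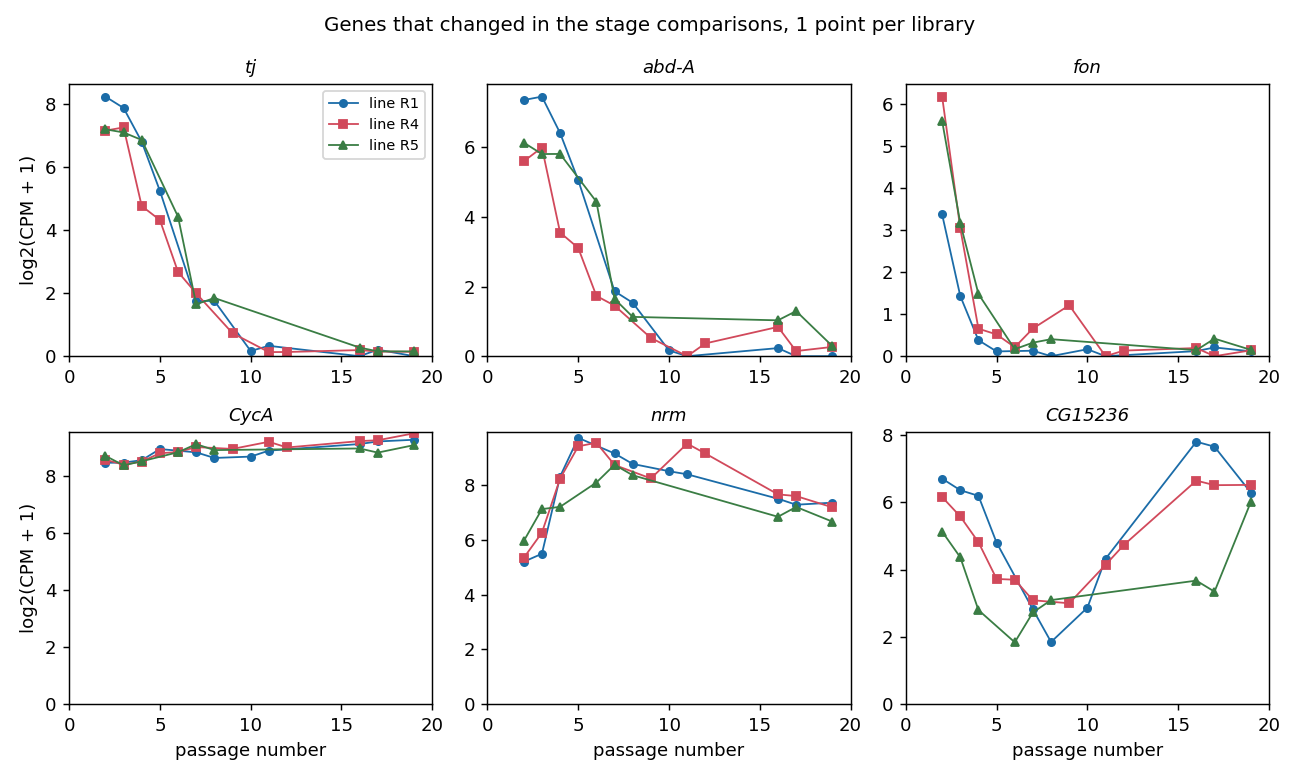
Level of tj, abd-A, fon, CycA, nrm and CG15236 against passage number, as log2(CPM + 1) with 1 point per library, coloured by line. tj falls from 155 CPM at early to 0.108 at late on average, and nrm stands highest at the intermediate stage (482 CPM).

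Of 14 measured antimicrobial and humoral immunity genes, 8 fell (AttB, Drs, BomS1, DptA, Mtk, AttC, TotA and DptB), or 9 adjusted over the list alone. Drs, the antifungal peptide drosomycin, fell from 39.9 ± 19.0 to 2.94 ± 0.447 CPM (log2 -3.69 ± 0.49, adjusted p = 0.0122), and AttB, the antibacterial peptide attacin B, from 2.65 ± 1.57 to 0.0961 ± 0.0351 (log2 -4.62 ± 0.54, adjusted p = 0.00919). The list's median log2 change was -4.16 (camera adjusted p = 1.87e-07, or adjusted p = 0.678 with an estimated correlation). Without passage 2, AttB did not pass (log2 -1.96, adjusted p = 0.104), nor without R4 at passage 2 alone (log2 -3.59, adjusted p = 0.0639), and Drs changed by -2.36 on the log2 scale. Of 5 fat body genes 3 fell, also 3 adjusted over the list alone. fon, a secreted coagulation protein, fell from 18.8 ± 13.1 to 0.129 ± 0.0478 CPM (log2 -6.87 ± 0.60, adjusted p = 0.00466). Without passage 2 its log2 change was -4.47, and its early mean was 10.5 CPM without R4 at passage 2 and 12.5 without R5 at passage 2. apolpp, the lipophorin precursor, fell from 131 ± 75.7 to 12.98 ± 4.61 CPM (log2 -3.24 ± 0.44, adjusted p = 0.0126). Fbp1 fell from 4.99 ± 2.05 CPM to 1 late read, a ratio of 479 (95% counting interval 85.6 to 18938). The median of the fat body list was -3.24 (camera adjusted p = 0.0139, or adjusted p = 0.678 with an estimated correlation).

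Hox genes, which set segment identity along the body axis, also fell, 4 of 7 (abd-A, Ubx, Dfd and pb), or 5 adjusted over the list alone. abd-A fell from 83.0 ± 57.2 to 0.4664 ± 0.431 CPM (log2 -7.38 ± 0.84, adjusted p = 0.00845) and Dfd from 4.86 ± 3.71 to 0.616 ± 0.862 (log2 -3.64 ± 0.50, adjusted p = 0.0126). The median was -3.28 (camera adjusted p = 0.00237, or adjusted p = 0.678 with an estimated correlation). Of 16 epithelial junction genes 2 fell, or 5 adjusted over the list alone. These were baz, the polarity protein Bazooka (230.2 ± 39.7 to 101 ± 5.21 CPM, log2 -1.16 ± 0.24, adjusted p = 0.0360), and ed, the adhesion protein Echinoid (183 ± 33.2 to 76.4 ± 24.9, log2 -1.32 ± 0.28, adjusted p = 0.0392). Their list had a median of -0.37 (camera adjusted p = 0.0177, or adjusted p = 0.678 with an estimated correlation). Its medians by line were -0.51 in R1, -0.40 in R4 and -0.03 in R5. ed did not pass without R1 at passage 5, R4 at passage 3 or R5 at passage 19 (log2 -1.34, -1.26 and -1.27, adjusted p = 0.0528, 0.0545 and 0.0508), and Dfd (log2 -2.999, adjusted p = 0.223) and baz (log2 -1.20, adjusted p = 0.0539) did not pass without the line block.

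Among 36 cell cycle genes 13 rose and none fell, or 28 and none adjusted over the list alone. With DESeq2 25 rose and none fell, and at an unadjusted p under 0.05 28 rose and none fell. CycA, the mitotic cyclin A, rose from 363 ± 10.3 to 585 ± 73.1 CPM (log2 0.68 ± 0.10, adjusted p = 0.0160), and pav, the kinesin Pavarotti of cytokinesis, from 111 ± 4.38 to 174 ± 27.7 (log2 0.64 ± 0.09, adjusted p = 0.0149). aurB, fzy, tum, Incenp, borr, dup, Mcm7, CycB3, polo, stg and RnrL rose as well. The median was 0.45 (camera adjusted p = 2.00e-09, or adjusted p = 0.678 with an estimated correlation). Of 14 Notch pathway genes 3 rose, also 3 adjusted over the list alone. The Notch ligand gene Ser rose from 41.9 ± 12.2 to 92.6 ± 45.9 CPM (log2 1.09 ± 0.19, adjusted p = 0.0248), and E(spl)malpha-BFM, a target of the pathway, from 10.8 ± 2.44 to 20.5 ± 3.40 (log2 0.93 ± 0.18, adjusted p = 0.0312), with E(spl)m7-HLH as the third. The Notch list had a median of 0.88 (camera adjusted p = 0.0217, or adjusted p = 0.678 with an estimated correlation). Its medians by line were 1.39 in R1, 0.53 in R4 and 0.04 in R5. Ser lost the call without the line block (log2 1.15, adjusted p = 0.179), and E(spl)malpha-BFM without passage 2 (log2 0.73, adjusted p = 0.0847), also of R4 alone (adjusted p = 0.0615) or R5 alone (adjusted p = 0.0520).

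Cytosolic ribosomal protein genes had a median log2 change of 0.15 over 40 genes (camera adjusted p = 0.000744, or adjusted p = 0.678 with an estimated correlation). By line it was 0.16 in R1, 0.10 in R4 and 0.03 in R5. RpLP1 was the 1 gene called, and 0 passed adjusted over the list alone, against 10 higher and 0 lower at an unadjusted p under 0.05 and 5 higher with DESeq2. RpLP1 went from 730.0 ± 85.4 to 916 ± 27.1 CPM (log2 0.33 ± 0.08, adjusted p = 0.0490), and the call was lost when scaled by median of ratios (adjusted p = 0.0590) or to total counts (0.0753), without the filter (0.0961), with the stricter filter (0.0720), with passage 4 as intermediate (0.113), with limma-trend (0.0548), without the line block (0.112), with passage 12 added (0.0574), with any line left out (0.0527 to 0.423) and with 22 of the 31 libraries left out in turn. RpL8 stood at 892 ± 89.6 CPM at early and 1173 ± 186 at late (adjusted p = 0.0531). Glycolysis genes had a median of -0.30 over 13 genes (camera adjusted p = 0.0139, or adjusted p = 0.678 with an estimated correlation). None of them passed alone over all genes in edgeR, against 4 lower adjusted over the list alone (Gapdh2, Pfk, Ald1 and Pgi), 6 lower at an unadjusted p under 0.05 and 6 lower with DESeq2. Gapdh2 stood at 475 ± 38.0 CPM at early and 364 ± 44.4 at late (adjusted p = 0.0661).

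**Figure D3:**
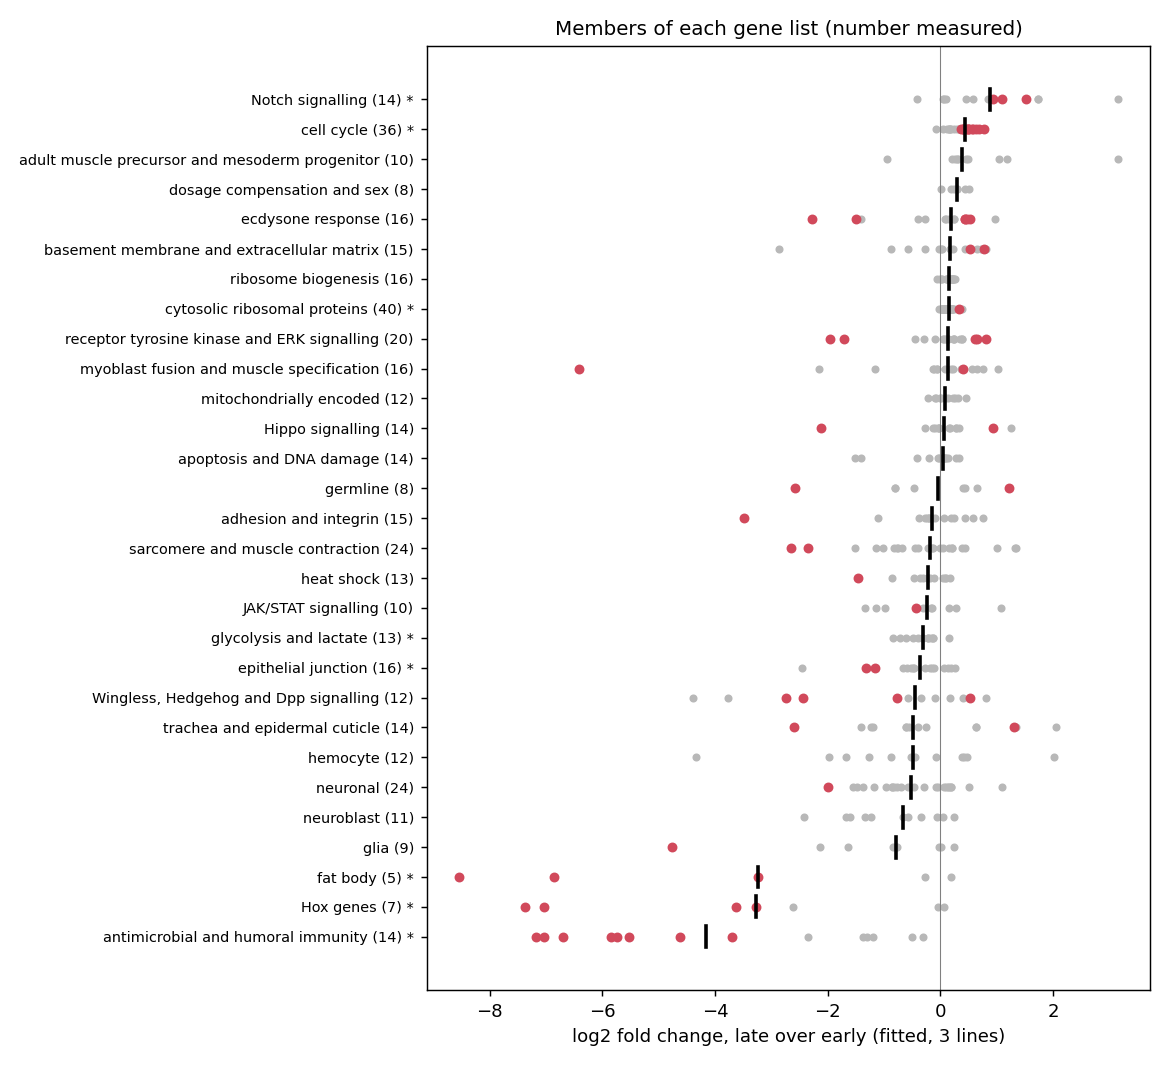
Late minus early log2 change of each measured member of the 29 gene lists, 1 point per gene, with members past the adjusted threshold in red, the others in grey, the median as a black bar and an asterisk for lists called by camera with the preset correlation. Antimicrobial and humoral immunity has a median of -4.16 and cell cycle one of 0.45, and no list passed with an estimated correlation (adjusted p = 0.678 for each of the 8 called, 1 list at an unadjusted p under 0.05, and 4 lists with fry).

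Signalling lists that were not called by camera held single genes that changed. Among 20 receptor tyrosine kinase and ERK genes 3 rose and 2 fell, the same adjusted over the list alone (adjusted p = 0.270 for the list, median 0.14, mean -0.000823). Egfr, the EGF receptor, fell from 43.4 ± 13.2 to 13.1 ± 2.85 CPM (log2 -1.72 ± 0.14, adjusted p = 0.00466), as did its ligand vn (log2 -1.96 ± 0.41, adjusted p = 0.0379). The feedback inhibitor genes sty (1964 ± 135 to 3009.7 ± 444 CPM, log2 0.61 ± 0.09, adjusted p = 0.0137) and aos (324 ± 98.0 to 569.8 ± 169, log2 0.81 ± 0.12, adjusted p = 0.0145) rose, together with rho. Among 16 ecdysone response genes 4 rose (EcR, Eip74EF, Hr39 and Eip63E) and 2 fell (Eip75B and Blimp-1), the same adjusted over the list alone (adjusted p = 0.489, median 0.20, mean -0.11). Eip75B fell from 106 ± 37.5 to 37.8 ± 14.8 CPM (log2 -1.50 ± 0.12, adjusted p = 0.00442). Of 12 Wingless, Hedgehog and Dpp genes brk rose and dpp, fz3 and ci fell, or 1 and 5 adjusted over the list alone (adjusted p = 0.158). Of 14 Hippo genes ft rose and ds fell, or 6 and 1 adjusted over the list alone (adjusted p = 0.489). Of 10 JAK/STAT genes Stat92E fell, or 2 adjusted over the list alone (adjusted p = 0.296).

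Markers of single cell types were mostly not called. Of 24 sarcomere genes 2 fell, also 2 adjusted over the list alone (adjusted p = 0.147), and Act79B, a muscle actin, went from 415 ± 129.8 to 65.3 ± 21.3 CPM (log2 -2.65 ± 0.29, adjusted p = 0.00716), with TpnC73F as the other. Of 16 myoblast fusion and muscle specification genes blow rose and bin fell, the same adjusted over the list alone (adjusted p = 0.561, median 0.14, mean -0.37). Of 9 glia genes alrm fell from 44.5 ± 39.0 to 1.23 ± 0.663 CPM (log2 -4.77 ± 0.65, adjusted p = 0.0126), and 1 rose and 5 fell adjusted over the list alone (adjusted p = 0.0674). Of 24 neuronal genes VGlut fell (log2 -2.002 ± 0.43, adjusted p = 0.0405), and 0 passed adjusted over the list alone, against 2 lower at an unadjusted p under 0.05 and 2 lower with DESeq2 (adjusted p = 0.0988 for the list). The median log2 change of the neuronal list was 0.30 in R1, -0.67 in R4 and -1.60 in R5. Of 8 germline genes krimp rose and pgc fell, the same adjusted over the list alone (adjusted p = 0.676). Of 14 trachea and epidermal cuticle genes btl rose and pio fell, the same adjusted over the list alone (adjusted p = 0.676).

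Among 11 neuroblast genes edgeR called none, against 3 lower adjusted over the list alone, 3 lower at an unadjusted p under 0.05 and 3 lower with DESeq2 (adjusted p = 0.0539 for the list). The median log2 change of this list was -0.01 in R1, 0.06 in R4 and -2.99 in R5. None of 12 hemocyte genes passed in edgeR, nor adjusted over the list alone, against 1 higher and 2 lower at an unadjusted p under 0.05 and 2 lower with DESeq2 (adjusted p = 0.517). None of 10 adult muscle precursor and mesoderm progenitor genes passed in edgeR, nor adjusted over the list alone, against 2 higher at an unadjusted p under 0.05 and 1 higher with DESeq2 (adjusted p = 0.147). One gene of that list, twi, stood at 30.7 CPM in R5 at passage 19 and at 130.1 and 137 at passages 16 and 17.

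Of 15 adhesion and integrin genes the integrin beta subunit gene Itgbn fell, also 1 adjusted over the list alone, from 44.3 ± 1.76 to 4.26 ± 1.80 CPM (log2 -3.48 ± 0.32, adjusted p = 0.00545, with 0.270 for the list). Of 15 basement membrane and matrix genes LanB1, a laminin chain, rose from 1087 ± 25.5 to 1901 ± 531 CPM (log2 0.77 ± 0.14, adjusted p = 0.0264) and Mmp2 rose as well, or 2 rose and 1 fell adjusted over the list alone (adjusted p = 0.489, median 0.17, mean -0.02). Of 13 heat shock genes Hsp67Ba fell, also 1 adjusted over the list alone (adjusted p = 0.246). None of 14 apoptosis and DNA damage genes passed in edgeR, nor adjusted over the list alone, against 2 higher and 1 lower at an unadjusted p under 0.05 and 1 higher with DESeq2 (adjusted p = 0.877, median 0.04, mean -0.18). None of 12 mitochondrially encoded genes (adjusted p = 0.517) and none of 16 ribosome biogenesis genes (adjusted p = 0.147) passed in edgeR, adjusted over the list alone, at an unadjusted p under 0.05 or with DESeq2. None of 8 dosage compensation and sex genes passed in edgeR, adjusted over the list alone or with DESeq2, against 4 higher at an unadjusted p under 0.05 (adjusted p = 0.0539).

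The 12 genes named in every case gave 0 calls from early to late in edgeR and 0 in DESeq2, with 2 at an unadjusted p under 0.05. Ras85D, the fly Ras gene, stood at 1037 ± 181 CPM at early, 908 ± 272 at intermediate and 1308 ± 223 at late (adjusted p = 0.163). twi, the mesoderm transcription factor Twist, stood at 89.8 ± 25.8 and 185 ± 73.1 CPM at early and late (adjusted p = 0.321), and within R4 it rose from 65.8 ± 29.8 to 230.2 ± 22.0 CPM (adjusted p = 0.0118). The muscle regulator genes zfh1 (125 to 158 CPM), Mef2 (40.5 to 52.8) and Him (25.3 to 17.7) had adjusted p of 0.208, 0.0903 and 0.672. Act57B (4.40 to 5.77 CPM), the hemocyte gene Hml (29.9 to 36.9), the neuronal gene elav (185 to 176) and Myc (632 to 626) had adjusted p of 0.866, 0.924, 0.689 and 0.989. The dosage compensation RNAs roX1 (1004 to 1306 CPM) and roX2 (192 to 275) had adjusted p of 0.280 and 0.204. N, the Notch receptor gene, stood at 349 and 485 CPM (adjusted p = 0.127).

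The timing of these differences was taken from the 2 steps, early to intermediate and intermediate to late. From early to intermediate 888 genes changed, 336 upward and 552 downward, and from intermediate to late 7 changed, 2 upward and 5 downward (1007 at an unadjusted p under 0.05). With 1 library left out in turn the later step called 0 genes in edgeR (without R1 at passage 5, 866 at an unadjusted p under 0.05, other tools not used here) to 13, and the first step 386 without R4 at passage 2. tj fell in both steps, with log2 changes of -4.19 ± 0.20 (adjusted p = 0.000821) and -6.26 ± 0.30 (adjusted p = 0.00374). Its second step was not called without the first intermediate library of a line, R1 at passage 5 (log2 -5.51, adjusted p = 0.2605, with -5.01 in the first step), R4 at passage 5 (-5.92, 0.0636) or R5 at passage 6 (-5.85, 0.0505), so the division of the fall between the steps depends on these libraries. The first step called fon (log2 -5.97 ± 0.54, adjusted p = 0.00779), Drs (log2 -2.47 ± 0.47, adjusted p = 0.0323) and abd-A (log2 -3.68 ± 0.65, adjusted p = 0.0285), and pav rose in it (log2 0.50 ± 0.09, adjusted p = 0.0315). Drs lost the first step without R1 at passage 2 (adjusted p = 0.0769), R4 at passage 2 (0.101) or R5 at passage 7 (0.0533). Its log2 change for fon was -4.87 without R4 at passage 2, and that for abd-A -4.65 without R1 at passage 5.

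A few genes turned back. nrm, an immunoglobulin-domain adhesion protein gene, rose from 113 ± 13.8 to 482 ± 123 CPM (log2 2.07 ± 0.13, adjusted p = 0.00249) and then fell to 157 ± 32.5 (log2 -1.61 ± 0.12, adjusted p = 0.0272). Its early level leaned on passage 4 in 2 lines. Without passage 4 the early mean was 39.7 rather than 131 CPM in R1 and 57.4 rather than 138 in R4. CG15236 fell from 52.4 ± 32.3 to 9.81 ± 3.97 CPM (log2 -2.30 ± 0.24, adjusted p = 0.0111) and rose to 98.0 ± 71.2 (log2 3.09 ± 0.24, adjusted p = 0.0272). Spn27A, a serpin that restrains Toll signalling and melanization, fell from 31.03 ± 5.12 to 12.9 ± 1.99 CPM (log2 -1.26 ± 0.08, adjusted p = 0.00337) and rose to 26.0 ± 5.56 (log2 0.998 ± 0.08, adjusted p = 0.0295). Limma-trend gave 0 genes for the later step (1001 at an unadjusted p under 0.05, and 290 with DESeq2). Without the line block 3 genes were called, none of them these: the later step had adjusted p of 0.156 for nrm, 0.429 for CG15236 and 0.399 for Spn27A, and the first step of CG15236 did not pass either (adjusted p = 0.109). Without passage 19 of R5 there were 3 genes, and CG15236 (adjusted p = 0.235) and Spn27A (adjusted p = 0.0620) were lost. The later step gave 1 gene without R1, 0 without R4 (407 at an unadjusted p under 0.05) and 104 without R5. With passage 4 as intermediate, the later step of nrm (adjusted p = 0.269) and Spn27A (adjusted p = 0.08145) did not pass, nor did that of Spn27A without passage 2 (adjusted p = 0.0508). Left out in turn, 5 single libraries ended the later step of nrm (adjusted p up to 0.311, without R1 at passage 4), 4 that of CG15236 (up to 0.235, without R5 at passage 19) and 8 that of Spn27A (up to 0.114, without R4 at passage 2). For the first step the count was 349 without the block, 21 without R1, 6 without R4 and 313 without passage 2, and total-count scaling gave 179 rises and 582 falls.

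Each line was next taken as its own time series. From early to late 2544 genes changed in R1 (1149 upward, 1395 downward), 2834 in R4 (1298 and 1536) and 1605 in R5 (712 and 893). A total of 479 changed the same way in every line, 137 upward and 342 downward, where independent changes would give 12.6 and 22.7. tj was among them, with log2 changes of -11.66 ± 2.00 in R1, -9.65 ± 1.88 in R4 and -9.72 ± 1.88 in R5 (adjusted p between 0.000135 and 0.000637, edgeR). CycA rose in each line, by 0.70 ± 0.11, 0.84 ± 0.11 and 0.43 ± 0.11 in R1, R4 and R5 (adjusted p between 1.12e-05 and 0.00630). Another 115 genes changed in opposite directions in different lines.

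The size of the change differed between lines for 1173 genes. Chance was not excluded for this count (see the splits below). The p-values measure the spread between successive passages of a culture. CngA, a cyclic nucleotide-gated channel gene, rose from 59.0 ± 4.05 to 571 ± 36.1 CPM (SD, n = 3 libraries) in R1 and from 54.3 ± 3.46 to 347 ± 51.3 in R4, and fell from 22.1 ± 6.97 to 1.58 ± 1.14 in R5 (adjusted p of the difference = 1.99e-05). Root, which encodes rootletin of the ciliary rootlet, rose from 1.39 ± 0.260 to 63.7 ± 15.0 CPM in R1, and stood at 1.57 ± 0.484 and 1.88 ± 0.340 in R4 and 1.16 ± 0.271 and 0.919 ± 0.567 in R5 (adjusted p of the difference = 3.32e-07). N rose in R1 (log2 0.95 ± 0.13, adjusted p = 1.00e-05) with log2 changes of 0.20 ± 0.13 in R4 and 0.11 ± 0.13 in R5 (adjusted p of the difference = 0.00386). Him fell in R4 (log2 -3.12 ± 0.65, adjusted p = 0.00101) and had a log2 change of 1.01 ± 0.54 in R1 (adjusted p of the difference = 0.00466). mwh, a wing hair polarity gene, rose from 0.457 ± 0.0474 to 18.5 ± 3.15 CPM in R1 and from 0.446 ± 0.191 to 27.6 ± 41.3 in R5, and stood at 0.492 ± 0.283 and 0.412 ± 0.0911 in R4 (adjusted p of the difference = 0.0129, but 0.0701 without R4 at passage 2 and 0.08435 with the passage block). The late R5 libraries of mwh held 7.20, 0.560 and 74.8 CPM at passages 16, 17 and 19, so that passage 17 was near the early level and the mean without passage 19 is 3.88.

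**Figure D4:**
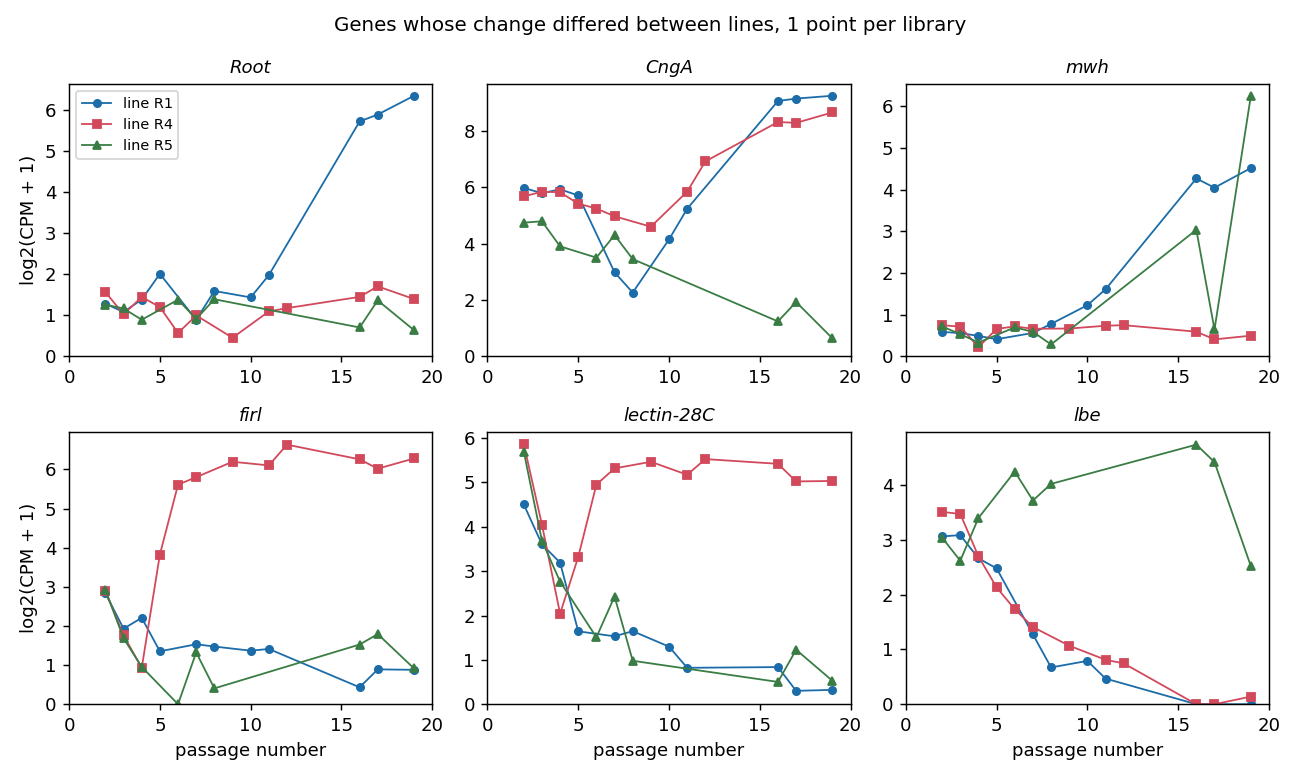
Level of Root, CngA, mwh, firl, lectin-28C and lbe against passage number, as log2(CPM + 1) with 1 point per library, coloured by line. Late means of Root are 63.7 CPM in R1, 1.88 in R4 and 0.919 in R5, and those of firl 0.679, 72.2 and 1.75.

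The established cultures were then compared with each other. At the late stage 4246 genes differed between the lines. R1 was highest for Cht12, a chitinase gene (15.4 ± 3.34 CPM, against 0.0241 in R4 and 0.111 in R5), which had no read in the early R1 libraries and was at least 211-fold higher at late. R1 was also highest for the Wnt receptor gene Drl-2 (18.0 ± 3.59 CPM, against 1.37 and 0.146), CG32204 (25.9 ± 3.14, against 0.330 and 0.401) and CG14110 (11.8 ± 2.28, against 0.212 and 0.145). R4 was highest for the C-type lectin gene lectin-28C (35.1 ± 5.92 CPM, against 0.423 in R1 and 0.737 in R5), which fell in R1 and R5 from 13.7 ± 7.08 and 22.8 ± 24.4 at early (8.84 in R5 without passage 2). R4 was also highest for the homeodomain gene unc-4 (67.8 ± 20.9 CPM, against 0.705 and 2.66, the last 0.844 without passage 17), firl (72.2 ± 7.13, against 0.679 and 1.75), CG33465 (56.9 ± 3.53, against 0.820 and 0.257) and CG32106 (17.8 ± 9.08, against 0.168 and 0.217).

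R5 was highest for the thick filament gene Prm, paramyosin (93.4 ± 45.3 CPM, against 1.02 in R1 and 0.978 in R4), and for the homeodomain genes HGTX (17.2 ± 6.42, against 0.0278 and 0.0719) and lbe (17.0 ± 10.9, against 0 and 0.0340). lbe had no late read in R1, at least 83.8-fold below its early level there, and 1 late read in R4, an early to late ratio of 289.8 (95% counting interval 51.7 to 11478). CG8492 stood at 154 ± 128 CPM in R5, at least 1723-fold above R4, which had no read, and Cpr11A, a cuticle protein gene, at 83.6 ± 92.2, against 0.251 in R1 and 0.307 in R4. These R5 means depend on 1 library each, CG8492 on passage 16 (80.2 without it) and Cpr11A on passage 19 (30.2 without it). The adjusted p of these late differences lay between 2.48e-11 (Root) and 4.81e-06 (lectin-28C) in the joint edgeR test.

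At the early stage 430 genes differed between the lines, or 660 with passage number as a block. R5 was highest for the Hox gene Antp (138 ± 39.2 CPM, against 17.0 ± 5.93 in R1 and 22.3 ± 14.7 in R4, adjusted p = 9.88e-05), Fam92 (58.4 ± 29.8, against 1.29 ± 1.23 and 0.465 ± 0.267, adjusted p = 1.27e-08) and frac (51.1 ± 49.8, against 1.95 ± 0.949 and 2.62 ± 1.58, adjusted p = 0.000308). In R5 frac stood at 2.78, 48.7 and 101.3 CPM at passages 2, 3 and 4, with a mean of 25.7 without passage 4, and it did not pass with passage 4 as intermediate (adjusted p = 0.0667). R1 was highest for CG6398 (36.5 ± 13.6 CPM, adjusted p = 0.00269), the junctophilin gene jp (109 ± 9.84, adjusted p = 0.0240) and Ubx (11.9 ± 2.77, adjusted p = 0.0412), and R4 for grn, a GATA factor gene (10.9 ± 6.62 CPM, adjusted p = 0.0121). Osi12 (30.4 ± 51.8 CPM) and CG11317 (32.9 ± 55.4) were highest in R4 with passage 4, and without it their adjusted p was 0.576 and 0.957. jp lost the call without any 1 early library of R1 (adjusted p 0.0626 to 0.0710) or without R5 at passage 3 (0.0588), and Ubx without any 1 of those of R1 (0.0750 to 0.146), R4 at passage 3 (0.0518) or R5 at passages 3 and 4 (0.102 and 0.101).

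With passage 4 counted as intermediate the early count was 64, and among these genes the calls of Antp and Fam92 held. It was 176 without R1 at passage 2, 261 without R1 at passage 3, 695 without R4 at passage 2, 233 without R5 at passage 3 and 239 without R5 at passage 4. The median absolute log2 difference between lines was 0.15 to 0.18 at early and 0.21 to 0.31 at late, and 368 to 619 genes at early and 981 to 1520 at late differed more than 2-fold between lines.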

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

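In this part, the test of depth, the intervals on the fat body test and the splits that keep passages apart were chosen after results were seen (the last before their own values), while the other tests were set before. Values far from the rest of their group were sought in the intermediate groups of R1 and R4 (5 libraries each), where 20 of 148 values met Dixon's 95% criterion, which chance alone meets about 5% of the time. For 5 of them (CG15293, Cpr49Ag and Dfd in R1, CG15369 and CG1468 in R4) the other 4 libraries had no read, so that any read meets it and this rate does not apply. Most of the 20 were at passage 5, the first passage of both groups.

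In R1, 8 genes at passage 5 stood above the other intermediate passages, with 4.82 CPM of CG14072 (0 to 0.189 in the others), 1.23 of CG34166 (0 to 0.189), 0.0817 of CG15293 (1 read, 0 in the others), 0.981 of Cpr49Ag (0), 0.572 of IM33 (0 to 0.128), 0.327 of Dfd (0), 4.90 of Ubx (1.09 to 1.78) and 9.89 of CG6398 (1.09 to 2.08). In R4 at passage 5, CG15369 stood at 0.288 CPM (0 in the others), CG14072 at 1.22 (0 to 0.240), CG1468 at 0.360 (0), Spn27A at 18.2 (10.5 to 12.2) and frac at 1.30 (0.377 to 0.561). Below the others there were CG33465 at 8.28 CPM (34.1 to 49.1), lectin-28C at 9.00 (29.98 to 43.2) and firl at 13.2 (47.8 to 72.2). In R1, zfh1 stood at 122 CPM at passage 8 (181 to 199 in the others) and CG32106 at 0.378 at passage 7 (0.119 to 0.163). In R4, Pfk stood at 278 CPM at passage 6 (79.3 to 111) and roX1 at 998 at passage 11 (703 to 731).

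Of the fat body and immune lists 11 genes were called lower at late (3 of 5 and 8 of 14 measured), and the values here are of these 11, chosen for having fallen. From passage 2 to passage 4 their median log2 change was -2.80 in R1, -5.80 in R4 and -4.60 in R5. The lower depth of the late libraries is too small to give these falls. Late totals were 0.801 of early totals, while the median ratio of these genes' reads was 0.0142. This test was largely settled beforehand, since CPM are scaled to library size and the genes were chosen for having fallen. Loss of fat body cells that may have been present in the first cultures stays open. Were such cells lost alone, the genes would fall alike. The SD between genes was 1.03 in R1, 1.17 in R4 and 1.17 in R5, above the bound of 1 set beforehand, so by that rule this loss would be argued against. After these values were seen, 95% intervals were added (0.717 to 1.80, 0.817 to 2.05 and 0.821 to 2.06) and the reading was changed to open, since they span 1 and counts at passage 4 are low. A fall in transcription and a loss of cells are not told apart here.

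The change from early to late differed between lines for 13 named genes by the joint edgeR test, given here as the highest minus the lowest line on the log2 scale with its adjusted p. CngA differed by 7.09 (R1 against R5, 1.99e-05), Root by 5.89 (R1 against R5, 3.32e-07), CG32106 by 6.31 (R4 against R1, 0.00184), mwh by 6.11 (R5 against R4, 0.0129), CG14110 by 5.49 (R1 against R4, 0.00419) and lectin-28C by 5.48 (R4 against R1, 0.00299). Him differed by 4.14 (R1 against R4, 0.00466), ssp6 by 2.46 (R1 against R5, 0.0183), N by 0.85 (R1 against R5, 0.00386) and elav by 0.55 (R1 against R5, 0.00672). Cht12 (12.24, 5.34e-05), lbe (10.49, 4.74e-05) and CG8492 (10.42, 0.00380) each had a group without a read, so the fitted differences depend on the prior count and are no bounds. Without R4 at passage 2 the adjusted p of mwh was 0.0701, and with the passage block 0.08435.

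Other splits of the libraries were counted for each comparison. For the 3 comparisons of stages and the 3 lines there were 10 splits each, too few for a share under 0.05. The real count and the highest of the other splits were 967 and 0 genes for late against early, 888 and 0 for intermediate against early, 7 and 0 for late against intermediate, 2544 and 0 in R1, 2834 and 417 in R4, and 1605 and 2 in R5, and in each the real split was the 1 with a count as large. For the gene lists, also with 10 splits, 6 gave as many lists as the real 8, the highest other 9, so chance is not excluded for the number of lists. Between the lines at late, 1 of 100 splits, the real one, gave as many as 4246 genes (highest other 2504). The libraries of a line are successive passages of 1 culture, which alone could set the real split apart. With 1 culture per line, this test cannot exclude chance differences between cultures. Between the lines at early, 9 of 100 splits gave as many as 430 genes (highest other 980), and the split by passage number gave 807, so chance is not excluded, and the split by passage called more genes than the split by line. These splits mix passages, which pair the early libraries. Among the 36 splits with 1 library of each passage in every group, 1, the real one, gave as many (highest other 179). These too are successive passages of single cultures, so chance differences between cultures are not excluded. With passage number as a block the early count was 660. For the change that differs between lines, 5 of 100 splits gave as many as 1173 genes (highest other 1814), so chance is not excluded. This turns on the draw, since an earlier draw of 100 gave 1, the real one (highest other 572). Among 100 splits with 1 library of each passage in every group 6 gave as many (highest other 2567), which does not exclude chance either.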

How the results depend on the processing

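The runs without passage 2, without passage 19 of R5 and, for the stages, with each of the 31 libraries left out in turn were chosen after the data were seen. The last gave 625 to 1023 genes from early to late, 386 to 1067 from early to intermediate and 0 to 13 from intermediate to late. The counts within each line, of genes changing in every line, of changes differing between lines and of late differences stayed within 1.5 times their value. This held under every alternative run for them. Among these were each early or late library of the groups compared left out in turn (R1 1699 to 2659, R4 2119 to 3112, R5 1129 to 1649, every line 346 to 580, change differing 862 to 1503, late 3537 to 3937) and, for the last 2, the passage block (1548 and 4372). Intermediate libraries were not left out for these counts. The comparisons of stages, with 3 lines as replicates, moved more. From early to late (967) the count was 1859 with DESeq2, 3721 with each passage as a sample, 484 without the line block, 644 without passage 2, 3617 with log2 passage number as a covariate and 34 to 1047 with a line left out. From early to intermediate (888) it was 1989, 4211, 349 and 313 under the first 4 of these and 6 to 887 with a line left out. From intermediate to late (7) it was 15 without the filter, 290 with DESeq2, 1668 with each passage as a sample, 0 with limma-trend, 3 without the line block, 3 without passage 19 of R5 and 0 to 104 with a line left out (407 at an unadjusted p under 0.05 without R4). Treating passages as samples sets the spread within a culture in place of that between lines; for the others the cause was not tested. Of the 8 gene lists, 0 passed camera with an estimated correlation and 4 passed fry (antimicrobial and humoral immunity, fat body, Hox and cell cycle). Epithelial junction, ribosomal protein, Notch and glycolysis genes passed neither (fry adjusted p = 0.0910, 0.142, 0.204 and 0.220). The estimated correlations of the 8 ran from 0.16 (Hox) to 0.66 (glycolysis), against the preset 0.01. Among all 29 lists 10 passed without the line block (the 8 among them), 11 without R1 (6 of the 8), 9 without R4 (7 of the 8) and 6 without R5 (each among the 8). The early difference between lines (430) was 64 with passage 4 as intermediate, 796 with DESeq2, 660 with the passage block and 176 to 695 with a library left out.

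For 83 results on named genes, 1229 of 1399 alternative values kept direction and side of the threshold, 122 fell below it, 23 passed it and 25 changed sign, each of a gene not called; the cause was not tested. The log2 change of Him was 0.25 without R4 (-2.62 to 0.25 with a line left out), and that of elav 0.092 without R5 (-0.21 to 0.092). Act57B was at -0.067 with limma-trend, -0.53 without R1 (-0.53 to 0.66 with a line left out) and -0.029 with passage as a covariate. The main fitted change was negative for Hml and positive for Myc, opposite to the direction of their mean CPM over the lines. Hml was at 0.10 with limma-trend, 0.30 without the block, 0.20 without R1, 0.35 without R5 (-0.69 to 0.35 with a line left out), 0.40 without passage 2 and 0.021 with passage as a covariate. Myc, near 0 throughout, was at -0.016 with median of ratios, -0.049 with total counts, -0.025 without the filter, -0.029 with the stricter filter, -0.021 with passage 4 as intermediate, -0.016 with DESeq2, -0.044 with passages as samples, -0.057 with limma-trend, -0.014 without the block, -0.015 with passage 12 added, -0.063 without R1 (-0.063 to 0.073 with a line left out), -0.025 without R4, -0.078 without passage 2 and -0.017 with passage as a covariate. Depth limits the falls that end in 0 to 3 reads, whose size is known only to the intervals given.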

Other observations

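In this part the tests of level and length bias, mixing, batch and mislabelling were chosen after the results were seen. Within R1 516 genes and within R4 306 fell from early to intermediate and rose again to late, each step past the adjusted threshold, and 164 did so in both lines, where independent sets would share 17.2. R5 had 50 such genes, 2 of them shared with R1 and 2 with R4. The genes named here were chosen after their values were seen. chinmo, a BTB zinc finger gene of temporal identity, stood at 690.3, 67.5 and 724 CPM at early, intermediate and late in R1, at 504, 64.9 and 369 in R4, and at 978, 1299 and 1008 in R5. Its 5 intermediate libraries of R1 lay between 16.95 and 213.8 CPM, the highest at passage 5 and the next at 50.1, and without passage 5 the mean is 30.5. eya, a transcriptional coactivator gene of the retinal network, stood at 13.6, 1.29 and 35.4 in R1, 16.1, 1.51 and 26.3 in R4 and 31.1, 37.1 and 11.5 in R5. Of the fixed lists, the neuronal one held 4 of these genes among 24 measured (scrt, Appl, onecut and fne, hypergeometric test over 29 lists, adjusted p = 0.0229). All 4 also fell in R5 at intermediate (log2 -1.98, -1.47, -1.10 and -2.58, adjusted p = 0.0267, 0.00117, 0.0199 and 0.00121), so their fall was not confined to R1 and R4. The opposite course, a peak at the intermediate stage, was taken by 365 genes in R1 and 153 in R4, with 32 shared against 6.08 for independent sets. Both steps of a line use the same intermediate libraries, which inflates these counts within a line.

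Intermediate libraries mislabelled for line are argued against. A wrong passage label within a line was not tested. Over 3796 genes that differed between the lines at late, with genes that dip in any line left out, each of the 13 intermediate libraries lay nearest to the late mean of its own line by root mean square log2 difference. The ratio of that distance to the one to the nearest other line was 0.484 to 0.886 for 12 libraries, under the bound of 0.9 (upper ends of 95% bootstrap intervals over genes 0.515 to 0.941). R1 at passage 5 was above the bound at 0.922 (upper end 0.985), so its label was weighed apart. With it left out 193 genes dipped in both R1 and R4, so it is not the source of the pattern. These tests replaced one on centred correlations. A batch shared by libraries of like passage number, which may act on all 3 lines, is argued against for the return, as far as R5 was sampled. In R5 the median late minus intermediate log2 change of the 164 genes was -0.12 (95% bootstrap interval -0.25 to -0.04), against 2.00 in R1 and 1.70 in R4. For the fall such a batch stays open, since the R5 median was -0.37 (-0.64 to -0.13), against -1.55 in R1 and -1.74 in R4, and 53 of the 164 genes fell in R5. The intermediate libraries of R5 are of passages 6, 7 and 8 only. A batch at other passages, or of R1 and R4 alone, was not tested. The bootstrap intervals given here resample genes, which are not independent replicates, and do not cover the spread between libraries. The 164 genes were chosen for their course in R1 and R4, which enlarges the medians of these lines. No biological explanation was tested.

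Genes at the left end of chromosome arm 3L rose as a block in R5. The first 233 expressed genes of the arm in the BDGP6.54 order, up to kst, stood a median of 0.45 log2 above the other genes at the intermediate stage and 0.64 (1.56-fold) at late, relative to early R5. The rise was 0.40, 0.41 and 0.49 at passages 6, 7 and 8 and 0.73, 0.61 and 0.53 at passages 16, 17 and 19. In R1 it was 0.24 at intermediate and 0.17 at late, and in R4 0.09 and 0.20. No other window of 233 neighbouring genes among 5394 was as high, except in R4 at intermediate, where 97 were. The end of the block was set on the R5 late changes, so its rank in R5 at late is no test of it. Neighbouring windows overlap, so they are not independent. The highest other window in R5 at late was at 0.19. The 66 genes of chromosome 4 had a median of -0.36 log2 in R5 at late, -0.17 in R1 and -0.04 in R4, relative to the other genes.

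Expression level or gene length is argued against as the source of the block, since 10000 lists of other genes matched on both reached 0.0628 log2 at most. R5 cells or reads mixed into R1 and R4 are argued against for the smaller rises there, which would need 22.4% and 27.3% of R5 material, while the highest of the 5 genes named for R5 reached 1.10% of its R5 level. Extra DNA copies of the block in a share of the R5 cells may account for it. Of the 233 genes 93.6% lay above the median of the other genes. The lowest, middle and highest groups of these genes by expression rose by 0.66, 0.63 and 0.63. These values met bounds set before they were seen. However, the block was cut out on the same R5 late changes, so a high share above the median was likely from the start. The rise was alike across expression levels, which does not tell extra copies from another source of a regional rise. DNA was not measured, base composition was not analysed here, and the hypothesis remains untested.

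The R4 library at passage 12 belongs to no stage. It held 120.5 CPM of CngA, between 56.7 at passage 11 and 319.9 at passage 16, 563 of nrm, 25.6 of CG15236, 98.1 of firl, 45.1 of lectin-28C and 97.3 of twi. It lay at -42.3 on the first principal component of log2 CPM, between R4 at passage 11 (-47.0) and R1 at passage 10 (-39.8). On the second component it lay at 22.6, against 21.8 and 1.83 for these libraries.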
